A study of Homo sapiens with 6 samples.

How the data were processed

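RNA was measured in MOLM-13, a human acute myeloid leukaemia cell line that carries the KMT2A::MLLT3 fusion. Cells were exposed for 8 h to 100 nM ZS3-046, described by the submitters as a PROTAC (a molecule that brings a target protein to a ubiquitin ligase for degradation) against TAF1, or to the vehicle DMSO, with 3 libraries in each group. Total RNA was column purified, and per the labels' protocols a service company removed ribosomal RNA, made the libraries and sequenced them on a HiSeq2500. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The replicate numbers were not treated as pairs.

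The authors deposited 1 file per library with whole-number read counts per gene, not normalized. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts from Subread 1.5.2 and the genome build GRCh38, with no role or order. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Each file held 58143 rows: 58051 Ensembl genes and 92 ERCC transcripts, the synthetic RNAs added to samples as a spike-in. The labels do not mention the spike-in, so when and in what proportion it was added is unknown. The ERCC rows were kept out of library sizes and tests. They held 2.36 ± 0.28% of all counts in DMSO libraries and 3.15 ± 0.28% in ZS3-046 libraries (mean ± SD, n = 3 each). Gene symbols and types came from a name table and from GENCODE release 29, which held 57447 of the 58051 genes. Start and end were the same as in the files for 55333 of them (96.32%), and printed coordinates are those of the files, counted from 1 on GRCh38.

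Counts in genes per library ran from 55360796 to 68267653. The deposited counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by edgeR's default expression filter, libraries were scaled by TMM factors, and a quasi-likelihood model with robust dispersion compared the groups with no other term. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values were computed by edgeR from the counts and the TMM-scaled library sizes, and are given as mean ± SD over 3 libraries. A simulation on the 18947 tested genes, with 200 changed by known folds and the dispersions of the real data, recovered 32.8% of the 1.5-fold, 56.7% of the 2-fold and 83.3% of the 4-fold changes. In it, 10 of 125 calls were false.

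Before the data were examined, 39 gene lists were fixed. The 36 with at least 5 tested members were compared with all other tested genes by camera with a preset correlation of 0.01. Camera with an estimated correlation, camera on ranks and fry, which asks whether a list's genes move 1 way on balance without reference to other genes, were alternatives. Genes named in the text follow a rule also fixed before the data were examined. It took all TFIID subunits; the 12 protein-coding genes with the largest rise and the 12 with the largest fall among those past the threshold, without overlap between groups and with a mean of at least 5 CPM in the higher group; up to 3 non-coding RNAs per direction; and up to 4 changed members of each list. It also took MYC, MYB, FLT3, BCL2, MCL1, CDKN1A, CDKN1B, CCND2, CCND3, HEXIM1, FOS, HOXA9, MEIS1, CRBN and VHL whatever their result. Some genes that the rule took are not reported here. Other members are named where they make up a count of 5 or fewer, and those were chosen after their values were seen.

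Alternatives were other scalings (RLE, upper quartile, library totals, the mitochondrially encoded mRNAs, and, chosen after seeing the data, the ERCC counts), DESeq2 1.42.0, limma-voom, other filters, protein-coding genes only, a threshold of 0.01, a replicate block and leaving out each library. A planned test of TATA motifs in promoters needs genome sequence and was not analysed here. Without a known strand setting, reads from overlapping genes cannot be told apart. Of 194 genes taken by the rule, 86 share exon bases with another gene, 32 of them over 10% of their exon bases. Among these, 45.9% of the exon bases of TAF10 lie in other genes, mainly ILK on the other strand. The share is 35.3% for TAF9, which overlaps AK6, and 42.4% for BRD7, which overlaps ADCY7. It is highest for TIFAB (52.9%), and is 38.3% for XAF1, 37.2% for IL16, 36.9% for MED11 and 33.4% for TRAC. Histone genes, HSPA1A and HSPA1B, ribosomal protein genes with their pseudogenes, and TAF1 with its retrocopy TAF1L have near-identical sequences, so their counts are uncertain. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.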

Results

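The data were RNA-seq read counts from 6 MOLM-13 libraries, 3 after 8 h with 100 nM ZS3-046 and 3 after 8 h with DMSO. They address what happens to gene expression when a degrader is directed at TAF1, the largest subunit of TFIID, the complex that recognises core promoters for RNA polymerase II. Counts in genes were 68267653, 56801471 and 63288086 in DMSO replicates 1 to 3 and 59003790, 55360796 and 57253261 in ZS3-046 replicates 1 to 3. The first principal component of log2 CPM held 83.6% of the variance and separated the treatments. ZS3-046 replicate 2 stood apart, with a score of 45.4 on the first component against 88.5 and 89.2 for replicates 1 and 3, and −47.6 on the second against 13.1 and 21.8. The coefficient of biological variation was 5.42% within DMSO, 19.1% within ZS3-046 and 5.33% between ZS3-046 replicates 1 and 3. No pair of replicates was close enough to be 1 library deposited more than once.

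**Figure D1:**
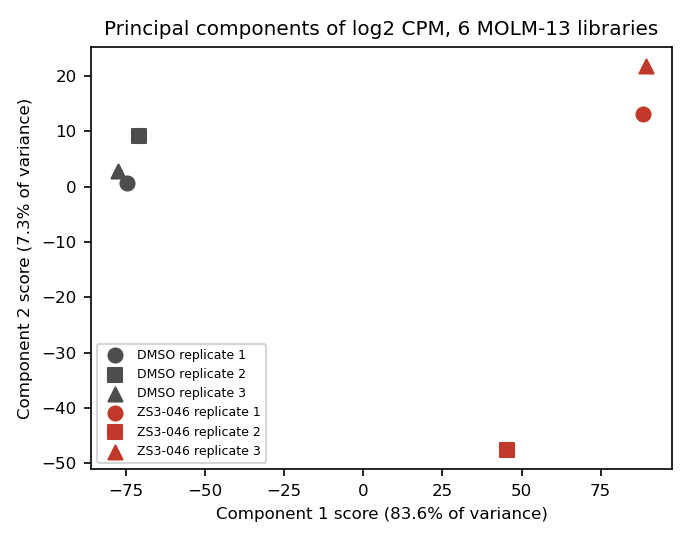
Scores of the 6 libraries on the first 2 principal components of log2 CPM, which hold 83.6% and 7.3% of the variance (grey, DMSO; red, ZS3-046; the marker shape is the replicate). The treatments separate on component 1, and ZS3-046 replicate 2 lies at 45.4 on component 1 and −47.6 on component 2.

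ZS3-046 changed the RNA of most tested genes. The cell cycle inhibitor CDKN1A (p21) rose from 215 ± 3.88 to 2961 ± 582 CPM, the P-TEFb inhibitor HEXIM1 from 65.6 ± 4.24 to 609 ± 114 CPM, and POLR2A, the largest subunit of RNA polymerase II, from 216 ± 8.59 to 1355 ± 268 CPM. The transcription factor MYB, on which many myeloid leukaemias depend, fell from 469 ± 29.4 to 205 ± 12.6 CPM, and the survival factor BCL2 from 192 ± 16.1 to 91.1 ± 4.45 CPM. Of 18947 tested genes, 10470 (55.3%) passed the threshold in edgeR's quasi-likelihood test, 5130 higher and 5340 lower, and 2845 were at least 2-fold higher and 1734 at least 2-fold lower. The groups did not overlap for 63.7% of tested genes, against 10% by chance. Protein-coding genes were more often lower (4641) than higher (3266), and pseudogenes and non-coding genes more often higher (529 and 1335) than lower (170 and 529).

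The balance of higher and lower genes depended on the scaling. With TMM, 51% of changed genes were lower and the median log2 fold change of all tested genes was 0.01. The lower share was 37.6% with upper-quartile scaling (median 0.18), 78.7% with scaling to the ERCC spike-in (median −0.48) and 82.4% with scaling to the mitochondrially encoded mRNAs (median −0.59). Under the ERCC and mitochondrial scalings the list medians of TFIID, RNA polymerase II subunits, p53 targets, cytosolic ribosomal proteins, nuclear-encoded respiratory chain genes, heat shock genes, glycolysis genes, housekeeping genes and epithelial and fibroblast markers turned from above to below 0. Under upper-quartile scaling those of Mediator, bromodomain proteins, elongation control, pro-apoptotic regulators, general transcription factors, NF-kB genes, interferon-stimulated genes, G2/M genes, proteasome subunits, zinc finger genes and T cell markers turned from below to above 0. All directions, medians and counts of higher and lower members given here are relative to the TMM scale unless another is named. They also shift with the scaling for lists where no other scaling is printed. Of the 36 lists tested 12 passed the camera test, and 0 of them with an estimated correlation, where fry called 25, and with no filter on low counts 24 passed. Without ZS3-046 replicate 2, 13247 genes changed, 6667 higher and 6580 lower.

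**Figure D2:**
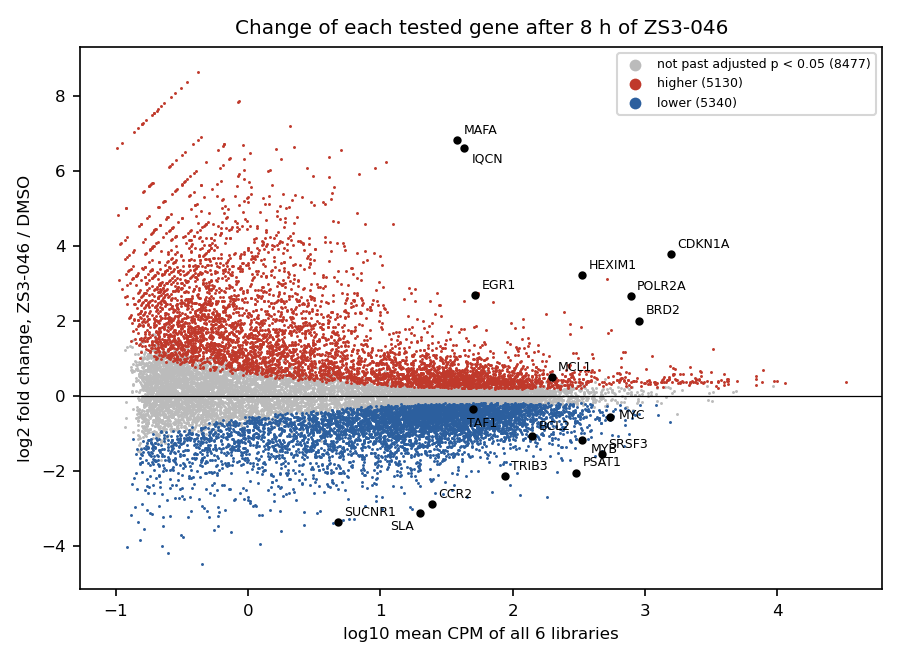
The log2 fold change of each of the 18947 tested genes (ZS3-046 over DMSO, vertical axis) against the log10 of its mean CPM over all 6 libraries (horizontal axis). Red points are the 5130 higher genes, blue points the 5340 lower genes and grey points genes not past the threshold. The largest rises lie among genes of low expression, and with scaling to the ERCC spike-in 78.7% of changed genes were lower in place of 51%.

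The largest rises were in genes nearly silent in these cells. MAFA (ENSG00000182759), a transcription factor of pancreatic beta cells, rose from 0.668 ± 0.0772 to 75.4 ± 27.3 CPM (log2 fold change 6.82 ± 0.34 SE, adjusted p = 6.56e-06). IQCN rose by 6.62 ± 0.58, reaching 84.4 ± 49.6 CPM, and TG, which encodes thyroglobulin, by 6.09 ± 0.49, reaching 18.1 ± 7.46 CPM. MGAM2, CILP, RRAD, CDKL2, ASTL, SNX31, TEX14, AOC3 and FAM131B rose by 5.24 to 6.55, each from under 0.3 CPM in DMSO. The largest falls were in SUCNR1, the succinate receptor, from 8.69 ± 0.912 to 0.840 ± 0.0833 CPM (−3.37 ± 0.16, adjusted p = 6.1e-06), and in INHBE, NLRP12, GPR18, SLA, TIFAB, IL16, ADM2, CD180, NOG and ZBED3 (−2.95 to −3.30). With no filter on low counts ADM2 was −3.08 and not past the threshold. CCR2, the chemokine receptor of inflammatory monocytes, fell from 43.2 ± 3.16 to 5.82 ± 2.45 CPM (−2.90 ± 0.25). Among non-coding RNAs, MIR223HG, the host gene of a myeloid microRNA, fell from 50.9 ± 1.18 to 8.31 ± 1.44 CPM (−2.62 ± 0.13) and CCDC26 from 24.0 ± 1.18 to 4.45 ± 0.533 CPM. MIR3648-1, typed as a microRNA by the annotation, rose from 0.896 ± 0.256 to 12.5 ± 0.429 CPM, and which RNA its reads came from was not tested.

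TFIID subunits moved in both directions. TAF1 (ENSG00000147133, chromosome X, 71366239 to 71532374, forward strand) fell modestly, from 56.3 ± 2.04 to 44.4 ± 1.76 CPM (−0.34 ± 0.07, adjusted p = 0.00401, lower in 3 of 3 libraries). It was −0.17 and not past the threshold with upper-quartile scaling. The degrader acts on protein, so TAF1 mRNA does not check the labels. TAF7, which binds TAF1, fell by 0.51 ± 0.08 on the log2 scale and TAF8 by 0.71 ± 0.11. TAF12 (0.70 ± 0.08), TAF13 (0.69 ± 0.08), TAF4B (0.56 ± 0.08), TAF6 (0.51 ± 0.08), TAF4 (0.49 ± 0.08), TAF3 (0.49 ± 0.11), TAF10 (0.42 ± 0.07), TBP (0.42 ± 0.07) and TAF5 (0.39 ± 0.10) rose on the TMM scale, and none was past the threshold as higher under the ERCC or mitochondrial scaling. TAF2, TAF9, TAF9B and TAF11 were between −0.18 and −0.06 and not past the threshold, though past it as lower under the ERCC and mitochondrial scalings. TAF2 was 0.005 without ZS3-046 replicate 1. Without ZS3-046 replicate 2, TAF9 (−0.23), TAF9B (−0.23) and TAF11 (−0.22) passed it. Of 16 subunits 9 rose and 3 fell, with the same counts adjusted over the list alone (median 0.40). On the TMM scale the list was not past the threshold against other genes (camera adjusted p = 0.22), and was past it upward by fry (adjusted p = 0.0156).

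The SAGA coactivator shares subunits with TFIID, and its list here left those out. Of the shared subunits, TAF10 and TAF12 rose on the TMM scale, and TAF9 and TAF9B were not past the threshold. Among the other SAGA subunits more fell than rose. Of 16 tested 10 fell and 1, TADA2B (0.34), rose, with the same counts adjusted over the list alone (median −0.30, camera adjusted p = 0.0229, adjusted p = 0.508 with an estimated correlation). With upper-quartile scaling 5 fell and 2 rose (median −0.13). The list was not past the threshold without ZS3-046 replicate 2 (median −0.28) or among genes with at least 50 counts (median −0.22), and TADA2B was not past it without any 1 DMSO library or without ZS3-046 replicate 1 or 3 (0.27 to 0.35). TADA1 fell from 17.3 ± 0.430 to 5.23 ± 1.85 CPM, SGF29 from 30.2 ± 0.292 to 11.6 ± 0.963, TAF6L from 20.7 ± 1.56 to 8.84 ± 1.28 and TRRAP from 70.5 ± 3.40 to 42.2 ± 5.80 CPM.

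Other parts of the transcription machinery changed gene by gene. Among 20 elongation genes 7 rose and 7 fell (2 and 12 with ERCC scaling), also adjusted over the list alone (median −0.05, mean 0.15, camera upward with adjusted p = 0.388). HEXIM1 rose by 3.22 ± 0.15, and its partner MEPCE, which caps 7SK RNA, by 0.95 ± 0.07. LARP7, which binds 7SK RNA, fell by 1.26 ± 0.16. Of 11 RNA polymerase II subunits 6 rose and 0 fell, also adjusted over the list alone (median 0.22, −0.28 with ERCC and −0.38 with mitochondrial scaling, camera adjusted p = 0.0532), led by POLR2A (2.65 ± 0.14). The list passed the test without ZS3-046 replicate 1 (median 0.28), 2 (0.21) or 3 (0.29), with a replicate block, with no filter, among genes with at least 50 counts and with upper-quartile scaling (0.39). Among 22 bromodomain genes, 2 rose and 8 fell (1 and 17 with ERCC scaling; 1 and 19 with mitochondrial scaling, where the list passed the test, as with no filter), also adjusted over the list alone (camera adjusted p = 0.28). BRD2 rose from 360 ± 3.90 to 1450 ± 277 CPM (2.01 ± 0.14), BRD8 rose by 0.45, CECR2 fell by 2.21 ± 0.19 and PBRM1 by 1.07 ± 0.10. Among 32 Mediator subunits 5 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.434), against 1 and 23 with ERCC scaling, and 1 and 28 with mitochondrial scaling, where the list passed the test, as with no filter. MED16 rose by 1.36 ± 0.08, MED26 by 0.78, MED15 by 0.56, MED29 by 0.33 and MED27 by 0.30, and MED11 fell by 2.06 ± 0.26. Of 17 general transcription factor genes (1 higher and 13 lower with ERCC scaling) 3 rose (GTF2A1 by 1.37 ± 0.10, GTF2E1 by 0.44, GTF2B by 0.39) and 4 fell (MNAT1, CCNH, CDK7 and GTF2H2), 3 and 3 adjusted over the list alone (median −0.10, mean −0.02, camera upward with adjusted p = 0.983). MED27 was not past the threshold without any 1 DMSO library (0.24 to 0.36), nor GTF2H2 (−0.41) without any 1 DMSO library or ZS3-046 replicate 1 or 3 (−0.45 to −0.28).

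**Figure D3:**
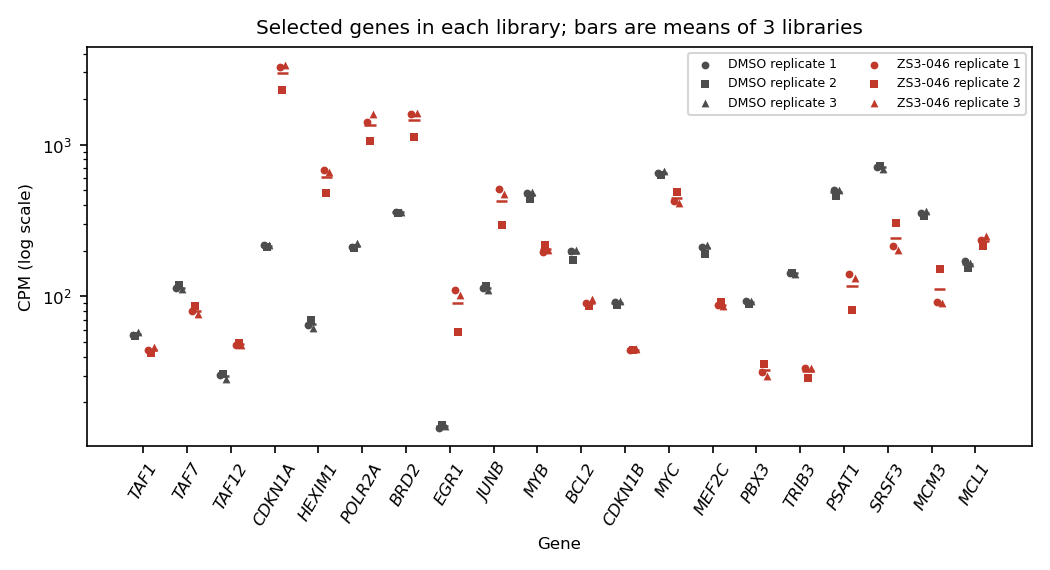
CPM on a log axis for 20 genes in each of the 6 libraries (grey, DMSO; red, ZS3-046; the marker shape is the replicate; bars are means of 3 libraries). CDKN1A, HEXIM1, POLR2A and BRD2 rose, MYB, BCL2, MEF2C and PBX3 fell, and TAF1 fell from 56.3 to 44.4 CPM. TAF12 and MCL1 rose on the TMM scale and were not past the threshold under the ERCC or mitochondrial scaling.

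Genes linked to the KMT2A::MLLT3 fusion in leukaemia fell. Of 29 tested, 24 fell and 1, HOXA7 (0.34), rose, with the same counts adjusted over the list alone (median −0.77, camera adjusted p = 4.93e-10, adjusted p = 0.508 with an estimated correlation). MEF2C fell from 207 ± 15.6 to 88.3 ± 3.02 CPM, PBX3 from 92.0 ± 2.49 to 32.6 ± 3.10, RUNX2 from 42.7 ± 0.806 to 14.98 ± 0.587 and HOXA5 from 6.22 ± 0.202 to 2.02 ± 0.504 CPM. MYB fell by 1.19 ± 0.08, MEIS1 by 0.68 ± 0.10, MYC by 0.56 ± 0.09, the receptor tyrosine kinase FLT3 by 0.42 ± 0.08 and HOXA9 by 0.37 ± 0.10. HOXA9 was not past the threshold without DMSO replicate 1 (−0.34) or with upper-quartile scaling (−0.20). HOXA7 was not past it without any 1 DMSO library or ZS3-046 replicate 1 or 3 (0.25 to 0.40). Survival genes did not move alike: BCL2 fell by 1.07 ± 0.09 and MCL1 rose by 0.50 ± 0.08 on the TMM scale (0.01 with ERCC scaling, −0.09 with mitochondrial scaling). BCL2A1 (−2.08 ± 0.22, from 2.07 ± 0.169 to 0.489 ± 0.0997 CPM), BCL2L2 (−0.84 ± 0.09), BCL2L1 (−0.60) and XIAP (−0.28) also fell. BIRC2 rose (0.61 ± 0.09, or 0.13 with ERCC and 0.02 with mitochondrial scaling and not past the threshold). Together these survival genes made 2 higher and 5 lower of 11 anti-apoptotic genes, also adjusted over the list alone (camera adjusted p = 0.243). Of 19 pro-apoptotic genes 2 rose, DIABLO by 0.27 among them, and 8 fell, also adjusted over the list alone (camera adjusted p = 0.0532), including BNIP3L (−1.61 ± 0.17), BIK (−1.24 ± 0.23) and CASP9 (−1.11 ± 0.14). That list passed the test without DMSO replicate 3 (median −0.10) or ZS3-046 replicate 2 (−0.12), on ranks, with library totals, with no filter, with a replicate block, and with ERCC (16 lower, −0.61) and mitochondrial scaling (19 lower, −0.72). XIAP was not past the threshold without any 1 DMSO library or ZS3-046 replicate 1 or 3 (−0.33 to −0.21) or with upper-quartile scaling (−0.12), nor DIABLO without any 1 DMSO library or ZS3-046 replicate 1 (0.26 to 0.28).

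Myeloid differentiation genes fell in part. CSF1R, the receptor that drives the monocyte lineage, fell from 12.5 ± 0.472 to 2.89 ± 0.388 CPM and FCGR1A from 33.2 ± 0.924 to 11.4 ± 0.612 CPM. CD14 rose from 0.240 ± 0.102 to 2.33 ± 1.14 CPM and FCER1G by 0.93. Of 22 tested monocyte genes 2 rose and 9 fell, with the same counts adjusted over the list alone (median −0.27, camera adjusted p = 0.0195, adjusted p = 0.508 with an estimated correlation). It was not past the threshold under the ERCC or mitochondrial scaling (medians −0.78 and −0.87). FCER1G was not past it without DMSO replicate 1 or 2 or ZS3-046 replicate 1 (0.74 to 0.91). Of 17 myeloblast and granule genes 9 fell, among them CD33 (−0.86 ± 0.08) and CEBPE (−1.46 ± 0.32), and 3 rose (AZU1 by 0.77, PRTN3 by 0.53, ELANE by 0.37), also adjusted over the list alone (camera adjusted p = 0.161), and the list passed the test with no filter and with mitochondrial scaling (13 fell and 0 rose). Without any 1 DMSO library PRTN3 (0.50 to 0.56) and ELANE (0.34 to 0.41) were not past the threshold, and PRTN3 was 0.26 without ZS3-046 replicate 2.

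Replication genes fell, and more p53 targets rose than fell on the TMM scale (8 rose and 11 fell with ERCC scaling, 8 and 12 with mitochondrial scaling). Besides CDKN1A (3.78 ± 0.15), the p53 targets TNFRSF10D (2.05 ± 0.17), TP53INP1 (1.79 ± 0.14) and FDXR (1.47 ± 0.07) rose, and EDA2R (−1.27), SESN2 (−1.12), the apoptosis effector BAX (−0.67), ZMAT3 (−0.44) and AEN (−0.35) fell. In all 13 of 27 p53 targets rose and 5 fell, also adjusted over the list alone (median 0.49, or 0.20 without DMSO replicate 2, camera adjusted p = 4.15e-04, adjusted p = 0.508 with an estimated correlation). With ERCC scaling the list was not past the threshold (median −0.03), and under mitochondrial scaling its median was −0.11. AEN was not past the threshold without DMSO replicate 1 or 3 or ZS3-046 replicate 1 (each −0.31), with upper-quartile scaling (−0.18) or among genes with at least 50 counts (−0.26). MCM3, part of the replicative helicase, fell from 352 ± 14.2 to 111 ± 34.0 CPM, MCM6 from 220 ± 15.1 to 99.4 ± 21.8 and E2F1 from 56.3 ± 2.98 to 19.4 ± 4.64 CPM. Of 46 E2F and replication genes 26 fell and 4 rose (RRM2 by 1.00, GINS4 by 0.37, E2F3 by 0.35, POLE by 0.26), 27 and 4 adjusted over the list alone (median −0.48, camera adjusted p = 2.92e-04, adjusted p = 0.642 with an estimated correlation). Without any 1 DMSO library GINS4 was not past the threshold (0.37 to 0.38), and without ZS3-046 replicate 2 it was 0.23. POLE was not past it without DMSO replicate 1 or 3 (each 0.25).

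Among 18 cyclin, G1 kinase and inhibitor genes 11 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.0805), and the list passed the test on ranks, with no filter and with mitochondrial scaling (15 fell and 1 rose). CDKN1A, CDKN1C (1.43 ± 0.35) and CCNE2 (0.40) rose, RBL1 fell by 1.21 ± 0.09 and the kinase inhibitor CDKN1B by 1.03 ± 0.07. CDKN1C stayed low, at 0.155 ± 0.0406 CPM in DMSO and 0.422 ± 0.0953 CPM after ZS3-046. CCND3 fell by 0.25 ± 0.07 and was not past the threshold without DMSO replicate 1 (−0.25), without DMSO replicate 3 (−0.25) or with upper-quartile scaling (−0.08). CCNE2 was not past it without DMSO replicate 1 or 2 or ZS3-046 replicate 1 or 3 (0.29 to 0.42). CCND2 was −0.09 ± 0.16 and not past it, with either sign when 1 library was left out (0.12 without ZS3-046 replicate 2, −0.24 without replicate 3), 0.09 with upper-quartile scaling, and past it as lower with ERCC (−0.57) and mitochondrial scaling (−0.69). Of 36 G2/M genes (0 higher and 23 lower with ERCC, 0 and 26 with mitochondrial and 18 and 8 with upper-quartile scaling) 11 rose on the TMM scale, among them CDC25B (0.72 ± 0.07), and 10 fell, among them TTK (−1.37 ± 0.18) and TOP2A (−0.74 ± 0.07), also adjusted over the list alone (camera adjusted p = 0.983). Of 33 double-strand break repair genes 17 fell, led by RAD51D (−2.07 ± 0.19) and NBN (−1.82 ± 0.13), and 4 rose, H2AX from 131 ± 11.3 to 411 ± 37.8 CPM, LIG4 by 0.54, XRCC3 by 0.49 and ATR by 0.39, also adjusted over the list alone (camera adjusted p = 0.0716). The repair list passed the test without DMSO replicate 2 (median −0.32) or ZS3-046 replicate 2 (−0.23), on ranks, with no filter, and with ERCC (27 lower, −0.76) and mitochondrial scaling (29 lower, −0.86).

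Immediate early genes, which respond to signals without new protein synthesis, mostly rose on the TMM scale, with 10 higher and 5 lower under ERCC scaling (median 0.42) and 10 and 6 under mitochondrial scaling (median 0.30). EGR1 rose from 13.9 ± 0.355 to 90.3 ± 28.2 CPM, JUNB from 113 ± 3.13 to 426 ± 114, BTG2 from 9.48 ± 0.182 to 42.7 ± 8.53 and IER3 from 8.77 ± 0.863 to 26.9 ± 12.4 CPM. FOS fell by 0.62 ± 0.10, NR4A1 by 0.84, KLF4 by 0.65 and MYC by 0.56 ± 0.09. IER3 was not past the threshold with no filter on low counts (1.57), nor KLF4 without any 1 DMSO library or ZS3-046 replicate 1 or 3 (−0.72 to −0.50). Of 26 members 20 rose and 4 fell, also adjusted over the list alone (median 0.89, camera adjusted p = 2.04e-04, adjusted p = 0.642 with an estimated correlation).

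Replication-dependent histone genes rose by the largest median of the tested lists. Of 49 tested 45 rose, 43 of them at least 2-fold, and 0 fell, also adjusted over the list alone (median 2.51, camera adjusted p = 3.32e-23, adjusted p = 0.523 with an estimated correlation). Levels stayed low: H3C10 went from 1.69 ± 0.486 to 19.0 ± 2.04 CPM and H2BC6 from 0.397 ± 0.0433 to 5.24 ± 1.89 CPM. These histone mRNAs normally lack a poly(A) tail. Of other RNAs without one, RN7SK, RN7SL1, RPPH1 and RNU6-7 had 0 counts in every library. Others such as RMRP (1 to 7 counts) and RNU6-9 (1 to 13 counts) were low but present, and RN7SL2 was tested. The handling of reads that map to several places is not given, so the zeros alone do not show whether such RNAs were lost. Whether the rise of histone counts reflects more histone mRNA or a change in how much of it the libraries captured was not tested. Low genes rose widely: of 1488 protein-coding genes with a mean under 0.5 CPM over all 6 libraries, 29.3% rose and 7.3% fell, against 19.2% and 43.4% of 5767 genes at 5 to 50 CPM. Of 18 RNA polymerase III transcripts 2 were tested, BCYRN1 (2.93 ± 0.296 to 5.34 ± 2.08 CPM) and RN7SL2 (0.19). RN7SL2 passed the threshold as higher with upper-quartile scaling (0.36), among genes with at least 50 counts (0.27) and without ZS3-046 replicate 2 (0.24). BCYRN1 rose, also adjusted over the list alone. BCYRN1 was not past the threshold without DMSO replicate 1 (0.86) or 3 (0.80), with ERCC (0.35) or mitochondrial scaling (0.28), and was 0.54 without ZS3-046 replicate 2.

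Cytosolic ribosomal proteins rose slightly and evenly on the TMM scale, and their median was −0.11 with ERCC scaling and −0.21 with mitochondrial scaling. Of 78 genes 74 rose and 0 fell, or 75 and 0 adjusted over the list alone (median 0.38, camera adjusted p = 2.12e-07, adjusted p = 0.642 with an estimated correlation). RPS15 went from 1160 ± 63.8 to 1652 ± 104 CPM. Under both of those scalings the list was not past the threshold. Genes for making ribosomes fell: 22 of 40 fell and 2, NOP2 (0.33) and NPM1 (0.20), rose, also adjusted over the list alone (median −0.44, camera adjusted p = 9.57e-04, adjusted p = 0.642 with an estimated correlation). NPM1 was not past the threshold without any 1 DMSO library or ZS3-046 replicate 1 or 3 (0.19 to 0.22). DKC1, a component of small nucleolar RNA complexes, fell from 256 ± 0.596 to 121 ± 17.2 CPM and the RNA acetyltransferase NAT10 from 176 ± 3.21 to 94.5 ± 0.995 CPM. The 13 mitochondrially encoded mRNAs rose, also adjusted over the list alone (median 0.59, or 0.10 with 0 of 13 past the threshold under ERCC scaling, camera adjusted p = 1.34e-05, adjusted p = 0.523 with an estimated correlation). MT-CYB went from 1282 ± 65.0 to 2104 ± 73.6 CPM. They took 2.23 ± 0.10% of gene counts in DMSO and 3.21 ± 0.09% after ZS3-046. Of 43 nuclear-encoded respiratory chain genes 19 rose and 2 fell, NDUFS1 by 0.59 ± 0.15 among them, or 17 and 2 adjusted over the list alone (median 0.24, −0.26 with ERCC and −0.35 with mitochondrial scaling, camera adjusted p = 0.076). The respiratory list passed the test without ZS3-046 replicate 1 (median 0.29) or 3 (0.31), on ranks, among genes with at least 50 counts and with upper-quartile scaling (0.41).

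**Figure D4:**
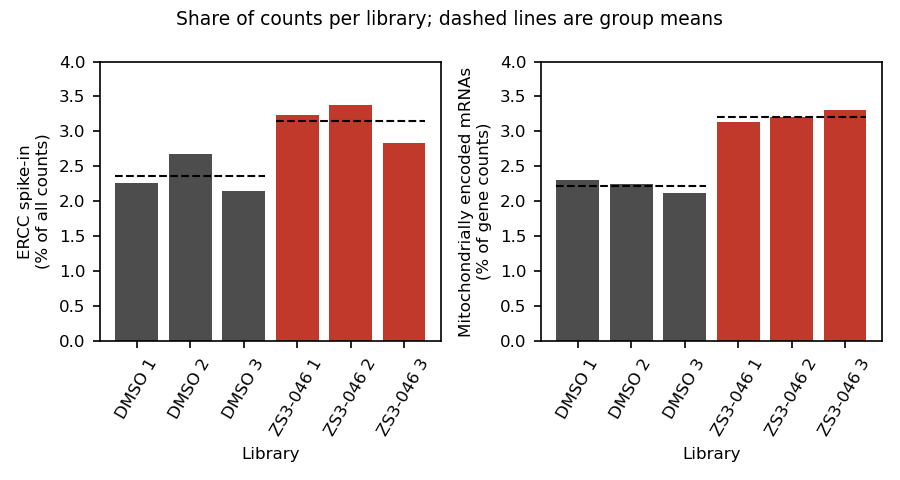
Percent of counts in each library taken by the ERCC spike-in (left, of all counts) and by the 13 mitochondrially encoded mRNAs (right, of gene counts), with dashed lines at the group means. The 3 ZS3-046 libraries lie above the 3 DMSO libraries in both, at means of 3.15% against 2.36% and 3.21% against 2.23%.

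Integrated stress response genes fell, most deeply in ZS3-046 replicate 2. The transcription factor ATF4 fell by 0.77 ± 0.21 (−0.50 without ZS3-046 replicate 2, and not past the threshold at −0.75 without DMSO replicate 2). TRIB3 went from 142 ± 0.790 to 32.1 ± 2.62 CPM, the serine synthesis enzyme PSAT1 from 488 ± 23.8 to 118 ± 31.8 and VLDLR from 60.5 ± 4.32 to 11.5 ± 1.26 CPM. PPP1R15A (1.14), CALR (0.79), HSPA5 (0.70) and HERPUD1 (0.69) rose, the last 3 of them linked to protein folding or degradation at the endoplasmic reticulum. Of 31 members 4 rose and 17 fell, 5 and 17 adjusted over the list alone (median −0.77, camera adjusted p = 4.15e-04, adjusted p = 0.642 with an estimated correlation). The median was −0.45, −1.17 and −0.51 in ZS3-046 replicates 1 to 3, and −0.42 without replicate 2. Splicing factors fell in part: SRSF3 went from 714 ± 15 to 241 ± 56.8 CPM, SRSF1 from 368 ± 10.6 to 142 ± 29 and HNRNPD from 700 ± 17.2 to 250 ± 101 CPM. Of 43 members 19 fell and 4 rose (SNRPD2 by 0.46, CLK1 by 0.38, PRPF31 by 0.27, SRSF11 by 0.26), also adjusted over the list alone (median −0.23, −0.36 without ZS3-046 replicate 2, camera adjusted p = 0.00396, adjusted p = 0.642 with an estimated correlation). The list was not past the threshold among genes with at least 50 counts (median −0.14). PRPF31 was not past it without DMSO replicate 1 or 3 (0.28 and 0.24), nor SRSF11 without any 1 DMSO library or ZS3-046 replicate 1 or 3 (0.23 to 0.28).

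Cholesterol synthesis genes did not pass the list test with all libraries (camera adjusted p = 0.356). Of 25 members 9 fell, SQLE by 1.33 ± 0.20, and 2, IDI1 (0.80 ± 0.16) and TM7SF2 (0.63), rose, also adjusted over the list alone. Without ZS3-046 replicate 2 the list passed the test, with 18 lower and a median of −0.40, as it did with no filter and with ERCC scaling of all 6 libraries (20 lower, median −0.70). Heat shock genes rose in 8 of 20 on the TMM scale, HSPA1B from 40.1 ± 1.88 to 155 ± 35.9 CPM and DNAJB4 by 1.09 ± 0.08, and CHORDC1 fell by 0.69, also adjusted over the list alone (median 0.20, −0.30 with ERCC and −0.40 with mitochondrial scaling, camera adjusted p = 0.0532). The heat shock list passed the test without ZS3-046 replicate 1 (median 0.23) or 3 (0.16), with no filter, among genes with at least 50 counts and with upper-quartile scaling (0.37). Of 33 interferon-stimulated genes (1 higher and 13 lower with ERCC scaling) 7 fell, led by XAF1 (25.9 ± 1.56 to 4.27 ± 0.769 CPM), and 4 rose (RSAD2 by 1.13 ± 0.27, IFI27 by 1.06, IRF7 by 0.61, ISG15 by 0.44), 7 and 3 adjusted over the list alone (camera adjusted p = 0.243). RSAD2 stayed low, going from 0.487 ± 0.116 to 1.065 ± 0.211 CPM. Of 25 NF-kB genes (3 higher and 14 lower with ERCC scaling) 6 fell, TNFAIP3 by 1.37 ± 0.19, and 5 rose (IER3, TRAF1 by 1.47 ± 0.32, TNF by 0.96 ± 0.17, TNFAIP2 by 0.54, CD83 by 0.42), also adjusted over the list alone (camera adjusted p = 0.61). Of 25 glycolysis and hypoxia genes (1 higher and 12 lower with ERCC scaling) 8 rose, ALDOC by 1.00 ± 0.12, and 5 fell, PDK1 by 1.51 ± 0.10, HK1 by 0.85 ± 0.17, PFKP by 0.61, SLC2A1 by 0.55 and PFKFB4 by 0.52, also adjusted over the list alone (camera adjusted p = 0.569). Of 31 proteasome subunits (0 higher and 27 lower with ERCC, 0 and 30 with mitochondrial and 8 and 3 with upper-quartile scaling) 3 rose on the TMM scale (PSMD2 by 0.52 ± 0.08, PSMA7 by 0.30, PSMD8 by 0.27) and 6 fell, PSMD14 by 0.56 ± 0.12, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.61). Calls lost without any 1 DMSO library were those of ISG15 (0.36 to 0.52) and PSMD8 (0.26 to 0.28), and PSMA7 was also lost without ZS3-046 replicate 1 (0.26 to 0.34). CD83 (0.35 to 0.43) and PFKFB4 (−0.61 to −0.37) were not past the threshold without any 1 DMSO library or ZS3-046 replicate 1 or 3.

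Among 11 ubiquitin ligase genes used by degraders 3 rose (BIRC2, ELOB by 0.57 ± 0.10, DDB1 by 0.29) and 6 fell, also adjusted over the list alone (camera adjusted p = 0.476). CRBN fell from 29 ± 0.904 to 16.0 ± 0.430 CPM and VHL by 0.30 ± 0.08. The VHL call was lost without DMSO replicate 3 (−0.26), without ZS3-046 replicate 1 (−0.23) and with upper-quartile scaling (−0.13), and that of DDB1 without DMSO replicate 1 (0.31) or 2 (0.22). Of 19 housekeeping genes (2 higher and 8 lower with ERCC scaling) 8 rose, POLR2A and ALAS1 (1.11 ± 0.08) among them, and 3 fell, IPO8 by 1.24 ± 0.19 and TUBB by 0.50 among them, also adjusted over the list alone (camera adjusted p = 0.137). Of 421 zinc finger genes 109 rose and 154 fell (36 and 231 with ERCC scaling), 111 and 157 adjusted over the list alone (median −0.08, mean 0.001, camera adjusted p = 0.326), with ZNF425 rising from 1.196 ± 0.102 to 16.7 ± 3.23 CPM.

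Some markers of other cell types changed. Of 5 tested T and NK cell markers TRAC fell from 30.9 ± 1.36 to 8.41 ± 0.678 CPM, CD3D fell by 1.08 ± 0.27 and CD8A rose to 0.504 ± 0.230 CPM (0 rose and 3 fell with ERCC scaling), also adjusted over the list alone (camera adjusted p = 0.153). The CD8A call was lost without DMSO replicate 2 (1.43) or 3 (1.25) and without ZS3-046 replicate 1 (1.28) or 3 (1.2). Of 4 tested B cell markers 2 rose, TNFRSF17 (to 0.280 ± 0.0638 CPM) among them, or 3 adjusted over the list alone. TNFRSF17 was not past the threshold without DMSO replicate 1 (1.11) or 2 (1.05) and without ZS3-046 replicate 1 (1.43) or 3 (1.08), nor with DESeq2 (1.27) or no filter (1.25). Of 2 tested erythroid and megakaryocyte markers ALAS2 rose to 0.368 ± 0.129 CPM and ITGA2B to 1.68 ± 0.908 CPM, also adjusted over the list alone. Of 6 tested epithelial and fibroblast markers COL1A1 rose, from 1.31 ± 0.0795 to 2.18 ± 0.298 CPM, and 0 fell, also adjusted over the list alone (camera adjusted p = 0.763).

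**Figure D5:**
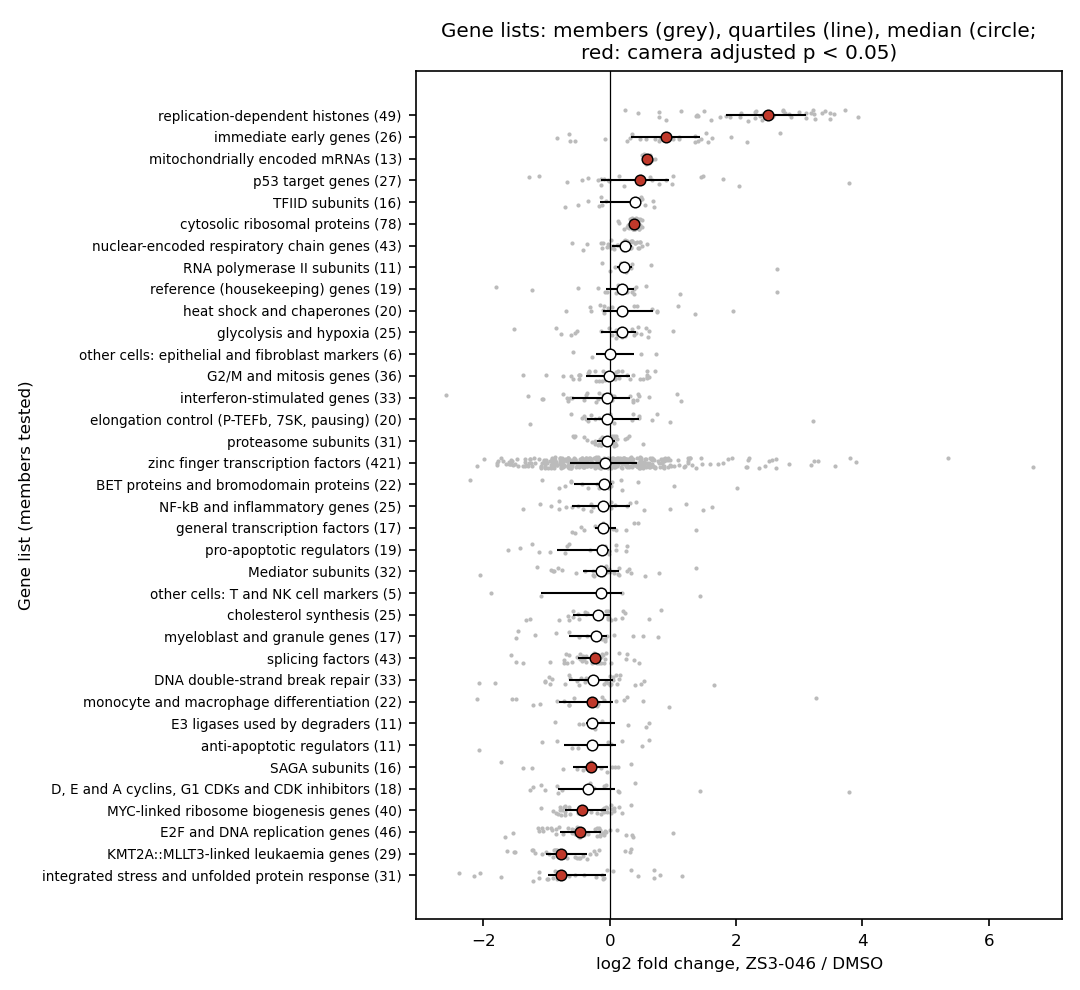
The log2 fold change (ZS3-046 over DMSO, horizontal axis) of the members of the 36 lists tested (grey points), with the quartiles (line) and the median (circle; red where camera adjusted p with a preset correlation is under 0.05). Histones have the highest median, 2.51, and 12 lists are red, of which 0 keep the call with an estimated correlation. The medians of TFIID, ribosomal proteins and p53 targets turn below 0 under the ERCC and mitochondrial scalings.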

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

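Of the tests here, the comparison of the spike-in and of mitochondrially encoded mRNAs with nuclear genes, the plain sums without the 100 most abundant genes, the setting of low genes by all 6 libraries and the other groupings of the libraries were chosen only after the result was seen. Groups of 3 libraries were not tested for outliers. The spike-in, which enters no comparison on the TMM scale, took a mean of 3.15% of all counts in ZS3-046 libraries against 2.36% in DMSO. Genes under 0.5 CPM in DMSO with no expressed gene within 50 kb, of which 1108 were tested and 12941 were outside the comparisons, summed to a mean of 839.1 ± 122.7 CPM in ZS3-046 libraries against 490.4 ± 20.5 in DMSO (SD, n = 3 each), and those not tested to 357.8 against 221.4.

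The spike-in rose against nuclear genes by 0.49 ± 0.13 on the log2 scale (SE, exact permutation p = 0.1, the smallest that 3 against 3 can give). Mitochondrially encoded mRNAs, which the spike-in cannot change, rose against nuclear genes by 0.597 ± 0.045. Against these mRNAs the spike-in did not rise (−0.103 ± 0.131 SE, exact permutation p = 0.6). A few abundant nuclear genes losing counts are argued against, since the 100 most abundant took a larger share after ZS3-046. They held 27.64 to 29% of nuclear counts in DMSO libraries and 32.74 to 36.74% in ZS3-046 libraries. Leaving them out therefore had to raise the spike-in against the plain sum of nuclear counts, by 0.586 ± 0.130 in place of 0.448 ± 0.126. Unequal addition may explain the spike-in part, since all 47 transcripts of the spike-in with at least 100 counts (100%) were higher, with quartiles of 0.48 and 0.52, and less nuclear mRNA per cell would do the same and may explain both parts. The treatment as the cause of either was not tested.

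More genes were detected after ZS3-046. Deeper sequencing is argued against, since with every library thinned to the same total the fewest genes in a treated library exceeded the most in a control by 1356. Transcription running past the end of an expressed gene may contribute: 15.7% of 1985 risen genes low in DMSO lay within 10 kb downstream of one against 9.0% of 2583 others (difference 6.6 points, 95% interval 4.7 to 8.6). With low set by all 6 libraries the difference was only 3.3 points (1.1 to 5.4). Among genes low in DMSO that overlapped no expressed gene it was 8.2 points (5.7 to 10.6, 17.7% against 9.5%). Risen genes also lay upstream of an expressed gene more often, where such transcription cannot act (9.0% against 6.3%), and overlapped one less often (28.5% against 34.2%). Background reads from DNA or unspliced RNA may also contribute. On the TMM scale the summed CPM of isolated low genes was 1.38 times higher in the lowest treated library than in the highest control. Of that rise 100 genes held 38.3%. With low set by all 6 libraries it was 1.24 times higher, and the treated mean was 1.49 times the control mean. Against nuclear genes the spike-in rose 1.41 times and mitochondrially encoded mRNAs 1.51 times, so the 1.49 depends on the scaling. Of the genes low by all 6 libraries, 10.4% were higher in every treated library than in every control, and 2.4% were lower. The 18 other groupings (2% on average) mix treated and control libraries, so they are no measure of chance. Transcription past gene ends and background reads both stay open, and activation of the low genes by the treatment was not tested.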

How the results depend on the processing

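The ERCC scaling was chosen after seeing the data, the other alternatives before the data were examined. The number of changed genes stayed within 1.5 times of 10470 under every setting run, from 7591 at a threshold of 0.01 to 13276 with mitochondrial scaling, and from 8384 to 13247 when 1 library was left out. With mitochondrial and ERCC scaling 2339 and 2499 genes were higher and 10937 and 9248 lower. At least 2-fold higher were 1810 with mitochondrial scaling, 4336 with no filter, 1372 among genes with at least 50 counts and 1482 among protein-coding genes. At least 2-fold lower were 5199 with mitochondrial scaling, 4392 with ERCC scaling and 1117 among protein-coding genes. Leaving out 1 library gave 4111 to 6667 higher and 4223 to 6580 lower genes, 2513 to 3295 and 1479 to 1994 of them at least 2-fold. The percent of changed genes that were lower was 49.48 with RLE, 56.18 with library totals, 37.64 with upper quartiles, 82.38 with mitochondrial scaling, 78.73 with ERCC scaling, 49.19 with DESeq2, 52.05 with limma-voom, 47.59 with no filter, 52.32 for protein-coding genes and 49.11 to 50.97 without 1 library. TAF1 was −0.17 with upper quartiles and −0.37 to −0.28 without 1 library. Of the lists 12 passed the test, 0 with an estimated correlation, 25 with fry, 24 with no filter and 12 to 15 without 1 library. The replicate block gave 9890 changed genes, 4788 higher and 5102 lower. Same-numbered libraries did not deviate together (correlations −0.051, −0.115 and −0.007), and the highest of the 9 was 0.134, between DMSO replicate 2 and ZS3-046 replicate 1. For 203 named genes, 3311 of 3645 values under the alternatives kept their side of the threshold and, where they were past it, their direction. Relative to mitochondrial scaling the log2 fold changes that turned negative were TAF3 −0.11, TAF4 −0.10, TAF4B −0.037, TAF5 −0.21, TAF6 −0.091, TAF10 −0.18, TBP −0.18, RPS15 −0.084, PSMD2 −0.079, ELOB −0.025, MCL1 −0.094, TADA2B −0.26, BRD8 −0.15, MED15 −0.039, MED29 −0.27, MED27 −0.29, GTF2E1 −0.15, GTF2B −0.20, HOXA7 −0.26, DIABLO −0.33, PRTN3 −0.067, ELANE −0.22, GINS4 −0.23, E2F3 −0.25, POLE −0.34, CCNE2 −0.21, LIG4 −0.058, XRCC3 −0.10, ATR −0.20, RN7SL2 −0.41, NOP2 −0.27, NPM1 −0.40, SNRPD2 −0.14, CLK1 −0.22, PRPF31 −0.32, SRSF11 −0.34, ISG15 −0.15, TNFAIP2 −0.059, CD83 −0.18, PSMA7 −0.29, PSMD8 −0.33, DDB1 −0.31. With ERCC scaling they were TAF3 −0.013, TAF5 −0.11, TAF10 −0.074, TBP −0.077, TADA2B −0.15, BRD8 −0.047, MED29 −0.16, MED27 −0.20, GTF2E1 −0.052, GTF2B −0.11, HOXA7 −0.17, DIABLO −0.23, ELANE −0.13, GINS4 −0.13, E2F3 −0.14, POLE −0.23, CCNE2 −0.097, XRCC3 0.000, ATR −0.10, NOP2 −0.16, NPM1 −0.29, SNRPD2 −0.039, CLK1 −0.10, PRPF31 −0.23, SRSF11 −0.23, ISG15 −0.051, CD83 −0.064, PSMA7 −0.20, PSMD8 −0.23, DDB1 −0.22. Called genes that kept their sign and were not past the threshold with both mitochondrial and ERCC scaling included TAF12 (0.11 and 0.21), CDKN1C (0.84 and 0.94), CDC25B (0.12 and 0.22), MT-CYB (0.12 and 0.23), RSAD2 (0.54 and 0.64), IDI1 (0.21 and 0.29), COL1A1 (0.14 and 0.23), MED26 (0.18 and 0.28), FCER1G (0.33 and 0.43), AZU1 (0.17 and 0.27), CALR (0.19 and 0.29), HSPA5 (0.10 and 0.20), HERPUD1 (0.10 and 0.21), TM7SF2 (0.03 and 0.13), IRF7 (0.02 and 0.14), CD8A (0.84 and 0.96) and TNFRSF17 (0.69 and 0.79). TNF (0.35) and IFI27 (0.45) were not past it with mitochondrial scaling, nor KLF4 (−0.48), ATF4 (−0.59), GTF2H2 (−0.24) and PFKFB4 (−0.36) with upper quartiles. DESeq2 lost the calls of TNFRSF17 (1.27), MED27 (0.28), HOXA7 (0.31), DIABLO (0.24), NPM1 (0.17), SRSF11 (0.23), PSMA7 (0.27) and PSMD8 (0.24), and limma-voom that of PRTN3 (0.48), for reasons not tested. The values under other scalings follow from the shift of the whole scale, by a median of −0.59 and −0.48 (0.18 with upper quartiles), and other causes were not tested. The planned test of promoter TATA motifs was not run. In the simulation 32.8% of 1.5-fold, 56.7% of 2-fold and 83.3% of 4-fold changes were recovered. It changed 200 of 18947 genes, against 10470 called in the data, and adjusted p-values depend on that share. Changes of each size were missed in it, and the recovery in the data themselves was not measured.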

Other observations

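The test of control RNA mixed into a library was chosen only after the result was seen, and the others here before it. Among expressed protein-coding genes, 31.8% of 1496 with a span up to 10 kb fell and 26.3% rose, against 43.7% and 14.6% of 1379 with a span over 100 kb.

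ZS3-046 replicate 2 stood apart from replicates 1 and 3. For genes changed at least 2-fold without it, its median log2 change was 1.28 for risen genes (1.83 and 1.86 in replicates 1 and 3) and −1.05 for fallen genes (−1.38 and −1.40), with 97.3% in the same direction. Control RNA mixed into the library could give such a weaker response, but the median log2 change of the stress response list, picked after its values were seen, was −1.17 in replicate 2 against −0.45 and −0.51, and a mixture with treated RNA like theirs would lie nearer 0. GC content and exon length accounted for 3.2% of the variance of its difference from the other treated libraries. Of 31 stress response genes 22 were below every other library in replicate 2, a shift in culture or handling stays open, and no biological explanation was tested.

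Fallen genes might have shared a promoter region with a divergent neighbour more often than others. Of 1298 protein-coding genes that fell at least 2-fold, 9.2% had a neighbour starting within 1 kb on the other strand, against 15.7% of other tested genes (difference −6.6 points, 95% interval −8.3 to −4.9), which is the opposite direction. Of 1390 genes that rose at least 2-fold 12.5% had one, against 15.4% of others (−2.9 points, −4.7 to −1), so the lower share was not particular to fallen genes.

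The 6 libraries can be split into 3 and 3 in 10 ways. The real split gave 10470 changed genes, the highest other split gave 0 in edgeR, and 1 split, the real one, gave as many as 10470. With 10 splits a share under 0.05 cannot be reached. Each other split also put treated and control libraries in both groups, so the difference between treatments became spread within groups. The 0 calls there are therefore no measure of chance.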
